A study of Homo sapiens
Mus musculus and Homo sapiens with 21 samples.

How the data were processed

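The human and the mouse table hold RPKM, reads scaled to transcript length and mapped reads, computed by the authors. Per the submitters' processing notes, reads were mapped to hg38 and mm10 (GRCh38 and GRCm38); the aligner and counting program are not given in the sources used here. RNA was total RNA taken with a kit for lipid-rich tissue, with standard Illumina libraries per the labels. Each library's RPKM is scaled to the reads of its own organism, so human values in tumour-free brain are shares of 3325 to 5753 reads. Human positions are from GENCODE 44 on GRCh38, and mouse positions are not given.

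The RPKM values of a gene are whole multiples of 1 step per library, and the reads behind them were recovered from those steps. Within 0.02, 100% of 33975 human and 32644 mouse genes above 0 gave whole numbers (17893 and 22583 seen in 10 or more libraries). Recovered totals were within 0.0655% (human) and 0.0555% (mouse) of the RPKM scaling. Of 33043 simulated genes, the 20802 so seen had 100% of reads exact, and totals were off by at most 0.149%. Reads give the depths, the expected misassigned reads and the alternative with voom. Intervals are of a median over genes and reflect spread between genes. A floor is 3 reads over a group and covers counting error only.

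RPKM was rescaled to a common sum per library within each organism, and log2(value + 1) was tested. The test was limma's moderated test with a trend and robust spread, in 1 fit of 13 libraries for human genes and 1 fit of 14 libraries for mouse genes, without a block. Genes with a rescaled value of at least 1 in at least 3 libraries of the fit were tested. P values are two-sided and adjusted by Benjamini and Hochberg over the genes of 1 comparison, and a call is an adjusted p under 0.05. An adjusted p beside a gene is from limma, and one beside a list is from limma's camera, adjusted over the 22 human or 30 mouse lists of the comparison, with a preset correlation of 0.01. Its adjusted p with estimated correlation stands beside it. Of 86 list calls, 13 held with estimated correlation. Folds are 2 to the power of the log2 change, pseudocount of 1 included.

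The comparisons, groups, filter, test, 52 lists, other settings and rule for naming genes were fixed before the data were examined. By that rule the 8 largest changes in each direction were named among calls with a mean of at least 5 in the higher group and no overlap between the sides, together with genes fixed per comparison and up to 4 of the largest called changes per called list. A few genes that meet this rule are not reported here. Cross-species genes have a mean in tumour-free brain (human) or the monolayer (mouse) of at least 0.1 times that of the tumour group. They were left out of the largest changes. Among calls that met the other limits of the rule, this left out 1051 higher ones in brain against subcutaneous tumours and 724 in tumour-bearing forebrain (1734 and 873 without those limits). The rule is severe, because background libraries are scaled to few reads: 4336 human genes tested met it, while 137 of 14557 had 25% or more of their metastasis reads expected from mouse RNA. Mouse reads expected at monolayer rates were 0.00219 and 0.00246% of mouse reads in forebrain and hindbrain metastases. No cross-species alternative was run for subcutaneous tumours against monolayer, and none with only the groups compared for the difference between regions.

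Libraries were taken as pairs where every same-number correlation of residuals passed 0.1 and exceeded those of other numbers. Tumour-bearing forebrain and hindbrain met this in mouse genes, with correlations of 0.24 to 0.44 against at most -0.04 between other numbers. In human genes of the same libraries the range was 0.04 to 0.07 against at most 0.01. The labels do not state which libraries came from 1 animal, and the counts with pairing had been seen when the rule was applied. Replicates differed beyond sampling of reads, with a chi-square per degree of freedom of 2.68 to 60.3 over 33 pairs.

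The tests were tested on simulated data with the depths of these libraries. A single dispersion of 0.005 (human) or 0.00545 (mouse) was used for all genes. The rates hold for that setting and need not hold here. From the first to the eighth comparison, changes of 2-fold were recovered in 95.5, 97, 89.6, 92.5, 98.5, 100, 97 and 97% of cases. False calls were 9.3, 6.4, 0, 33.5, 4.4, 2, 4.3 and 12.1% of calls in the same order. The rates of 33.5 and 12.1% are for 2 groups that are both shallower than the rest of their fit. With only the groups compared, false calls there were 11 of 159 between metastases and 7 of 201 between tumour-free regions.

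Alternatives added after the data were seen were voom on recovered reads, subtraction of human reads expected from mouse RNA, and leaving out replicate 1 of tumour-free forebrain and hindbrain together. R 4.3.3, limma 3.58.1, the package data.table in version 1.17.8, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used.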

Results

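RNA was sequenced from 21 libraries in 6 groups. They held H2030-BrM3 cells, a brain-seeking derivative of the H2030 human lung adenocarcinoma line, and brain or tumour tissue of athymic nude mice. The cells were grown as a monolayer (3 libraries) or as subcutaneous tumours (4 libraries). Tumour-free forebrain and tumour-free hindbrain gave 4 libraries each, and forebrain and hindbrain carrying metastases gave 3 libraries each. Tumours were dissected with the surrounding stroma, so human transcripts reported on the cancer cells and mouse transcripts on the host. The labels state the purpose as comparing cancer cells between environments and following the stroma of tumour-bearing brain.

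Monolayer libraries held 29579879 to 49599168 reads assigned to human genes. Subcutaneous tumours held 27253282 to 48152857 human reads and 2446513 to 3982107 mouse reads. Tumour-free brain held 17747167 to 23034782 mouse reads and 3325 to 5753 reads assigned to human genes, the background of the human values. Tumour-bearing brain held 52358082 to 86139353 mouse reads and 3579907 to 6897852 human reads, which were 4.83 to 7.52% of the library. In the monolayer, mouse genes took a mean of 0.0368 ± 0.0192% of reads (SD, n = 3). At the rates seen in tumour-free brain, mouse RNA accounted for 0.307% of the 27122953 human reads of the metastases. Values below are means ± SD of RPKM rescaled to a common sum per organism and library, and folds come from the limma fit on log2(value + 1).

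**Figure D1:**
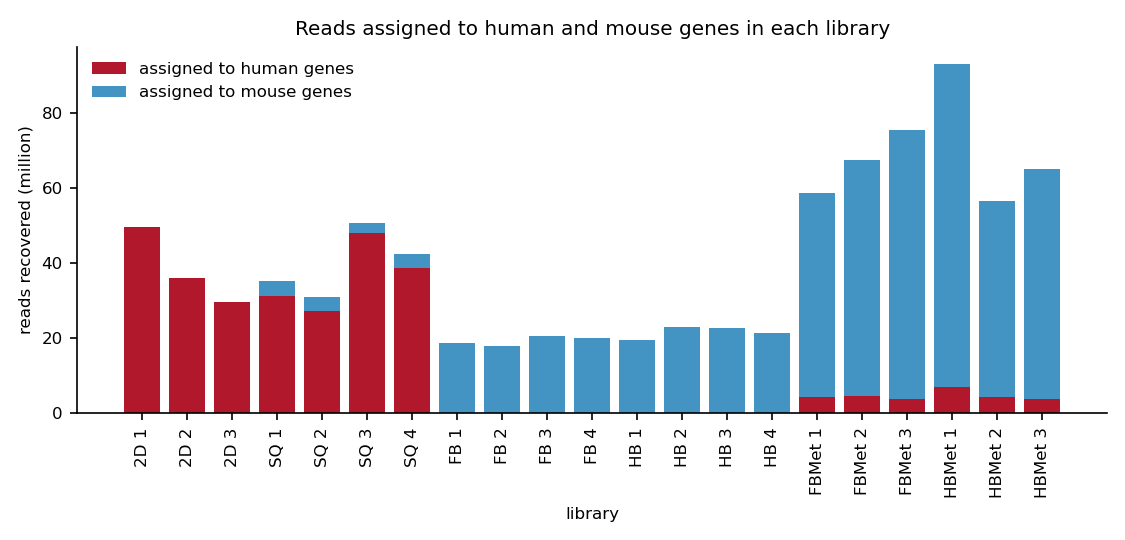
Reads recovered per library (axis in units of 1e6), stacked by organism of the gene they were assigned to. 2D is monolayer, SQ subcutaneous tumour, FB and HB tumour-free forebrain and hindbrain, FBMet and HBMet forebrain and hindbrain with metastases; the metastasis bars hold 3579907 to 6897852 human reads.

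The first comparison set cancer cells in brain (n = 6) against cancer cells under the skin (n = 4). THBS1 (ENSG00000137801.10, chromosome 15, 39581079 to 39599466 on GRCh38), the gene of the secreted matrix protein thrombospondin-1, was 25.2-fold higher in brain metastases (655 ± 134) than in subcutaneous tumours (24.9 ± 4.88), with 1104 ± 31.9 in the monolayer (n = 3). The transglutaminase gene TGM2 was 18.6-fold higher (715 ± 123 against 37.1 ± 4.24), and ANKRD1, a nuclear ankyrin repeat gene, was 13.8-fold higher (14.9 ± 2 against 0.147 ± 0.118). CDH1 (ENSG00000039068.18, chromosome 16, 68737292 to 68835537), which encodes the epithelial adhesion protein E-cadherin, was 5.12-fold higher (67.6 ± 5.81 against 12.7 ± 3.94) and stood at 0.901 ± 0.0865 in the monolayer. FOS (ENSG00000170345.9, chromosome 14, 75278826 to 75282230), an immediate early transcription factor gene, was 22.7-fold lower in brain (12.3 ± 4.57 against 349 ± 248).

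Other large increases in brain were the growth factor gene GDF6 (11-fold), the collagen receptor gene ANTXR1 (9.47-fold), SERTAD4 (9.06-fold), the matricellular gene POSTN (9.05-fold), the Wnt feedback inhibitor AXIN2 (8.57-fold) and PLAU, the gene of urokinase (8.16-fold). Other large decreases were the matrix link protein gene HAPLN1 (8.78-fold), FOSB (7.9-fold), the interferon-induced gene IFI6 (6.92-fold), EGR1 (5.9-fold), the mucin gene MUC16 (5.49-fold), the calgranulin gene S100A8 (5.35-fold) and the protease inhibitor gene SLPI (5-fold). Calls of FOSB and EGR1 were lost with voom. EPCAM, an epithelial surface glycoprotein gene, was 1.76-fold lower in brain (27.75 ± 8.69 against 47.7 ± 3.51). The mesenchymal filament gene VIM rose 1.43-fold and the transcriptional repressor gene ZEB1 1.79-fold. MKI67, a marker of cycling cells, rose 1.41-fold (69.9 ± 9.87 against 48.7 ± 1.41), and the neural adhesion gene L1CAM rose 1.83-fold (69.1 ± 7.97 against 37.2 ± 3.24). TUBB3, a neuronal tubulin gene, stood at 4.79 ± 1.5 against 6.47 ± 1.3 and did not pass (adjusted p = 0.0931), but passed with median-of-ratios scaling (adjusted p = 0.0462), nuclear genes (0.0493) and without subcutaneous replicate 1 (0.0403), forebrain metastasis replicate 1 (0.0319) or hindbrain metastasis replicate 2 (0.0318; 0.0318 to 0.253 over its alternatives). The lung lineage factor gene NKX2-1 and the astrocyte filament gene GFAP were too low to be tested in human cells.

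Among groups fixed in advance, 29 of 30 proliferation genes rose in brain (30 adjusted over the list alone). CCNA2 was 1.91-fold and TOP2A 1.81-fold higher (1709 ± 118 against 941 ± 43.1). For proliferation, camera gave adjusted p = 5.34e-11, and 0.323 with estimated correlation. Of 15 mesenchymal genes, 11 rose and 1 fell over all genes and over the list alone, with CDH2, the gene of N-cadherin, 2.75-fold and TGFBI 2.13-fold higher. The mesenchymal list passed camera with adjusted p = 0.00346 and had 0.162 with estimated correlation. Of 18 genes of serine, glycine and one-carbon metabolism, 12 rose and 1 fell (14 and 1 adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, rose 4.21-fold (23.1 ± 5.73 against 4.63 ± 0.881), MTHFD2 rose 2.14-fold and asparagine synthetase ASNS 2.02-fold. The serine and one-carbon list passed camera with adjusted p = 0.000679 and had 0.323 with estimated correlation. The epithelial list did not pass (5 of 14 rose and 2 fell over all genes and over the list alone; adjusted p = 0.28), although the keratin genes KRT8 (2.26-fold; 1147 ± 165 against 504 ± 44.1) and KRT18 (2.07-fold) rose.

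Of 19 hypoxia genes, 13 fell and 3 rose in brain (the same numbers adjusted over the list alone). The kinase gene PDK1 was 2.56-fold and ANGPTL4 2.21-fold lower. The hypoxia list passed camera with adjusted p = 0.000484 and had 0.323 with estimated correlation. Of 14 genes of MHC class I antigen presentation, 7 fell and 1 rose (same over the list alone): HLA-B fell 3.66-fold (4.34 ± 1.54 against 18 ± 1.91), HLA-F 2.74-fold and HLA-C 2.68-fold. The MHC class I list passed camera with adjusted p = 0.00151 and had 0.323 with estimated correlation. Of 19 type I interferon response genes, 9 fell and 1 rose (same over the list alone), with ISG15 2.9-fold and OAS1 2.31-fold lower. The interferon list passed camera with adjusted p = 0.00375 and had 0.34 with estimated correlation. Immediate early genes fell in 8 of 13 cases and rose in 2 (same over the list alone), NR4A1 by 3.9-fold. The immediate early list passed camera with adjusted p = 0.00205 and had 0.494 with estimated correlation. Cholesterol synthesis genes fell in 13 of 21 cases and 1 rose (14 and 1 over the list alone), with MVD 2.56-fold and DHCR7 2.22-fold lower. The cholesterol list passed camera with adjusted p = 2.06e-05 and had 0.323 with estimated correlation. Of 13 mitochondrially encoded genes, 11 fell (same over the list alone), MT-ND1 by 2.14-fold (camera adjusted p = 6.08e-07, and 0.323 with estimated correlation); quantile normalization ended this call. Glycolysis genes fell in 11 of 20 cases and rose in 3 (same over the list alone), with PFKFB4 3.07-fold lower and the glucose transporter gene SLC2A1 2.55-fold higher. The glycolysis list passed camera with adjusted p = 0.0166 and had 0.538 with estimated correlation. Leaving out cross-species genes ended the interferon and glycolysis calls.

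No camera call was made for 11 further lists. Neuronal genes rose in 6 of 16 cases and fell in 3 (adjusted p = 0.57), and synaptic receptors and channels in 5 and 2 of 8 (adjusted p = 0.476). Astrocyte genes did so in 2 and 3 of 8 (adjusted p = 0.209) and markers of other host cell types in 3 and 1 of 6 (adjusted p = 0.495), all the same over the list alone. Some of these transcripts matched mouse RNA in amount. Reads expected from mouse RNA were 99.6% of those of GAP43, 65.1% of those of SNAP25, 81% of those of GRIA3 and 73.3% of those of ZEB2, against 14.9% for VSNL1 and 0.0535% for CDH1. Lung lineage (0 of 6 rose, 1 fell; adjusted p = 0.708), inflammatory cytokines (3 and 3 of 13; adjusted p = 0.347) and collagens and basement membrane (4 and 8 of 19; adjusted p = 0.0814) gave the same numbers over the list alone. So did proteases and inhibitors (4 and 5 of 13; adjusted p = 0.57), brain metastasis genes from earlier studies (3 and 3 of 13; adjusted p = 0.513) and ribosomal proteins (9 and 1 of 24; adjusted p = 0.57). Oxidative phosphorylation genes rose in 7 of 25 cases (6 over the list alone) and fell in 4 (adjusted p = 0.734), and its median of 0.04 and mean of 0.03 differed in sign from the test. For proteases the mean was 0.19 and the median -0.11, and for lung lineage the mean was -0.05 and the median 0.02.

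Across the genome, limma called 7276 of 14557 genes, 4537 higher and 2739 lower in brain, of which 665 changed at least 2-fold. The balance of directions depended on scaling: median-of-ratios scaling gave 3349 higher and 3856 lower, scaling to nuclear genes 3478 and 3733, quantile normalization 3655 and 3524, and no filter on low values 4145 and 3865. The count was 4615 without the 4336 cross-species genes. Metastases of equal number may share an animal. The count was 7919 with metastases averaged by number. It was 6049 with the number as a block, which also joined subcutaneous and monolayer libraries of equal number.

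**Figure D2:**
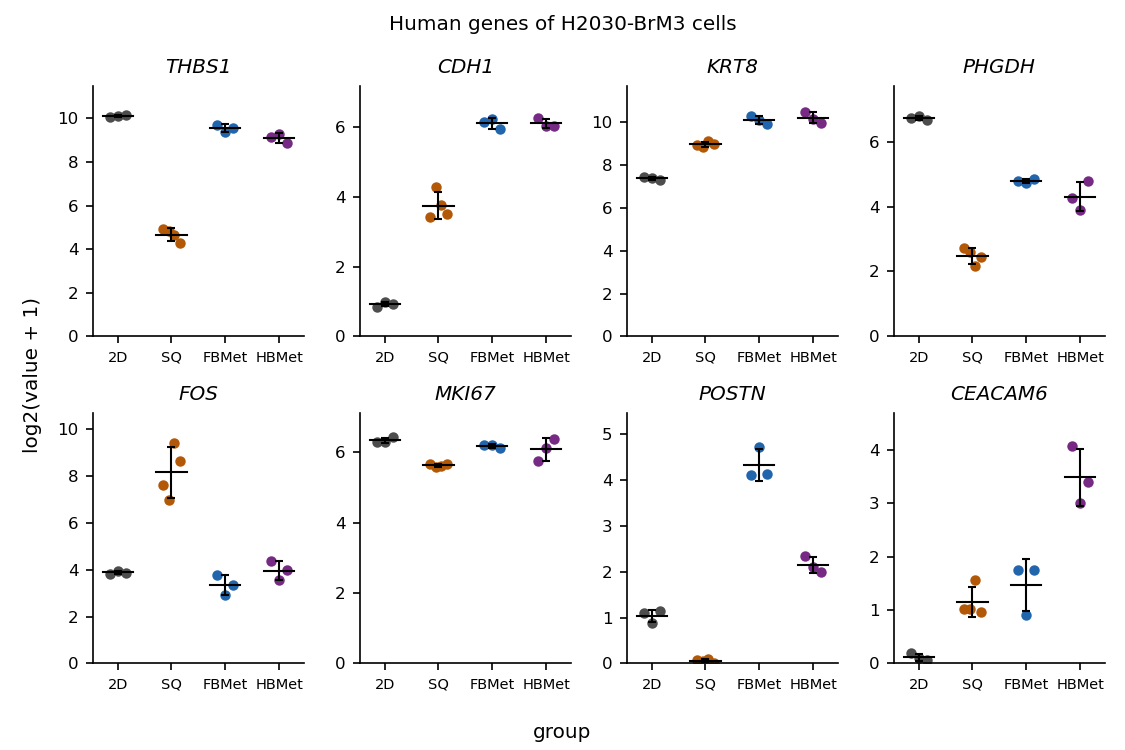
Human genes in log2(value + 1), where value is rescaled RPKM, in monolayer (2D, n = 3), subcutaneous tumours (SQ, n = 4) and forebrain and hindbrain metastases (FBMet and HBMet, n = 3 each). Points are libraries, lines are means and bars are SD; CDH1 averaged 67.6 in metastases, 12.7 under the skin and 0.901 in the monolayer.

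The second comparison set cancer cells in brain (n = 6) against the monolayer (n = 3). ALDH3A1, an aldehyde dehydrogenase gene, was 57.5-fold higher in brain (74.6 ± 13.3 against 0.302 ± 0.124), and CDH1 was 36-fold higher (67.6 ± 5.81 against 0.901 ± 0.0865). HP, which encodes the haemoglobin-binding protein haptoglobin, was 27.6-fold higher (145.5 ± 74.5 against 3.71 ± 0.14), and SPNS2, a transporter of sphingosine-1-phosphate, 26.2-fold higher. CYP1B1, a cytochrome P450 gene induced by the aryl hydrocarbon receptor, was 25.6-fold lower in brain (16 ± 2.9 against 430.4 ± 11), and TIPARP, a further target of that receptor, was 7.76-fold lower (6.32 ± 1.09 against 55.2 ± 0.934).

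The hyaluronan-degrading gene CEMIP (18.8-fold), the syndecan gene SDC2 (17.6-fold), the kinase gene CAMK4 (14.4-fold), GDF6 (13.4-fold) and the proteoglycan gene SPOCK1 (12.9-fold) were also higher in brain. The elongation factor gene EEF1A2 (12.1-fold), PRSS12 (7.73-fold), CLMN (7.5-fold), the fatty acid desaturase gene SCD (7.46-fold; 58.3 ± 10.3 against 436 ± 3.39), MSC-AS1 (6.66-fold) and F2RL2 (5.95-fold) were lower. EPCAM rose 2.12-fold, L1CAM 2.17-fold and SNAP25, with 65.1% of its reads expected from mouse RNA, 3.84-fold, while VIM fell 1.37-fold. ZEB1 rose 1.24-fold, a call lost without monolayer replicate 2 (adjusted p = 0.0588; 0.00187 to 0.0588 over its alternatives). MKI67 (69.9 ± 9.87 against 80.5 ± 4.23; adjusted p = 0.102) and TUBB3 (4.79 ± 1.5 against 3.63 ± 0.384; adjusted p = 0.276) did not pass, but MKI67 passed without hindbrain metastasis replicate 3 (adjusted p = 0.00792), with library weights (0.0132), with forebrain and hindbrain averaged by number (0.0257) and with voom (0.0495; 0.00792 to 0.3 over its alternatives).

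Epithelial genes rose in 9 of 14 cases and fell in 2 (same over the list alone), with KRT8 6.81-fold, KRT18 3.53-fold and the mucin gene MUC1 3.42-fold higher. The epithelial list passed camera with adjusted p = 0.000895 and had 0.0905 with estimated correlation. Neuronal genes rose in 11 of 16 cases and fell in 2 (same over the list alone): the calcium sensor gene VSNL1 rose 8.8-fold and the adhesion gene NCAM1 5.22-fold, while the adhesion gene CNTN1 fell 4.44-fold. The neuronal list passed camera with adjusted p = 0.00031 and had 0.0626 with estimated correlation. Mesenchymal genes rose in 8 of 15 cases (9 over the list alone) and fell in 3, with S100A4 8.5-fold higher (camera adjusted p = 0.0344, and 0.117 with estimated correlation); 5 alternatives ended this call. Markers of host cell types rose in 5 of 6 cases and fell in 1 (camera adjusted p = 0.0343, and 0.117 with estimated correlation), and 4 alternatives ended the call: no filter and a stricter filter on low values, leaving out cross-species genes and subtracting reads expected from mouse RNA. Of 13 mitochondrially encoded genes, 9 rose (same over the list alone), MT-ND3 by 2.49-fold (camera adjusted p = 0.00172, and 0.556 with estimated correlation).

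Serine and one-carbon genes fell in 15 of 18 cases (same over the list alone), with the stress-induced factor gene ATF3 5.35-fold, PHGDH 4.52-fold, ASNS 4.29-fold and the glutathione-degrading gene CHAC1 4.14-fold lower. The serine and one-carbon list passed camera with adjusted p = 8.07e-09 and had 0.101 with estimated correlation. Of 14 MHC class I genes, 10 fell (same over the list alone), HLA-B by 4.4-fold (4.34 ± 1.54 against 21.8 ± 1.01) and HLA-C by 3-fold. The MHC class I list passed camera with adjusted p = 9.92e-05 and had 0.117 with estimated correlation. Cholesterol synthesis genes fell in 13 of 21 cases and 1 rose (14 and 1 over the list alone), with INSIG1 3.29-fold lower. The cholesterol list passed camera with adjusted p = 0.000117 and had 0.311 with estimated correlation. Inflammatory cytokine genes fell in 6 of 13 cases (same over the list alone), CCL2 by 3.95-fold, CXCL8 by 3.52-fold and IL6 by 3.44-fold (camera adjusted p = 0.0194, and 0.523 with estimated correlation; lost without the filter on low values or without cross-species genes). Proliferation genes fell in 16 of 30 cases and rose in 2 (same over the list alone), with CDC20 1.58-fold lower and CENPE 1.66-fold higher. The proliferation list passed camera with adjusted p = 0.00112 and had 0.556 with estimated correlation. Ribosomal protein genes fell in 12 of 24 cases (13 over the list alone) and rose in 2. The ribosomal list passed camera with adjusted p = 0.00877 and had 0.612 with estimated correlation. Astrocyte genes fell in 5 of 8 cases (6 over the list alone) and rose in 1, with the glutamate transporter gene SLC1A3 4.26-fold lower (camera adjusted p = 0.0145, and 0.117 with estimated correlation; lost without the filter on low values).

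limma called 6247 of 14557 genes, 3192 higher and 3055 lower in brain, of which 810 changed at least 2-fold. The balance turned with median-of-ratios scaling (3065 higher and 3213 lower), quantile normalization (3005 and 3280) and no filter on low values (2765 and 3402). Leaving out cross-species genes gave 3891 calls (1894 higher and 1997 lower). The replicate number as a block gave 5912 and averages by number 6938.

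The third comparison set cancer cells under the skin (n = 4) against the monolayer (n = 3). HAPLN1 was 41.7-fold higher under the skin (48.8 ± 15.5 against 0.1496 ± 0.0502) and MUC16 31.9-fold higher (50.3 ± 5.39 against 0.608 ± 0.22). THBS1 was 43.2-fold lower (24.9 ± 4.88 against 1104 ± 31.9), the axon guidance-related gene NAV3 21.6-fold lower (2.54 ± 0.519 against 74.9 ± 3.53) and PHGDH 19-fold lower (4.63 ± 0.881 against 105.2 ± 3.56). CDH1 was 7.03-fold higher (12.7 ± 3.94 against 0.901 ± 0.0865).

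SPNS2 (21.4-fold), the matrix gene SNED1 (20.7-fold), FOS (19.4-fold), SPOCK1 (19.4-fold), the matricellular gene SPARCL1 (18.6-fold) and CYP4F12 (16.3-fold) were also higher under the skin. CYP1B1 (18.5-fold), the phosphatase gene UBASH3B (14.9-fold), FAM129A (14.7-fold), the peptide hormone gene APLN (13.2-fold) and CA8 (10.6-fold) were lower. EPCAM rose 3.72-fold, while VIM fell 1.96-fold, ZEB1 1.45-fold and MKI67 1.64-fold. TUBB3 rose 1.6-fold and L1CAM 1.19-fold, but these calls were lost in 4 and 9 alternatives. TUBB3 was lost without monolayer replicate 2 (adjusted p = 0.0685) or subcutaneous replicate 4 (0.0527; 0.000151 to 0.0685 over its alternatives). L1CAM was lost without any 1 of the 7 libraries except subcutaneous replicate 2 (0.0577 to 0.128; 0.000528 to 0.128 over its alternatives). SNAP25 stood at 0.569 ± 0.116 against 0.301 ± 0.104 (adjusted p = 0.285), but passed with voom (0.0074) and library weights (0.0362; 0.0074 to 0.668 over its alternatives).

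Proliferation genes fell in 29 of 30 cases (same over the list alone), with CDC20 2.33-fold, BUB1 2.29-fold and TOP2A 2.11-fold lower. The proliferation list passed camera with adjusted p = 8.09e-12 and had 0.219 with estimated correlation. Serine and one-carbon genes fell in 17 of 18 cases (same over the list alone), with ASNS 8.66-fold, CHAC1 5.69-fold and MTHFD2 4.48-fold lower. The serine and one-carbon list passed camera with adjusted p = 2.37e-09 and had 0.142 with estimated correlation. All 13 mitochondrially encoded genes rose (same over the list alone), MT-ND1 by 3.02-fold and MT-CYB by 2.9-fold. The mitochondrial list passed camera with adjusted p = 7.82e-09 and had 0.317 with estimated correlation. Epithelial genes rose in 8 of 14 cases and fell in 3 (same over the list alone), with MUC1 5.3-fold and KRT8 3.02-fold higher. The epithelial list passed camera with adjusted p = 0.0136 and had 0.214 with estimated correlation. Neuronal genes rose in 10 of 16 cases and fell in 2 (same over the list alone), the neurofilament gene NEFL by 5.08-fold and the secretory granule gene CHGB by 3.85-fold. The neuronal list passed camera with adjusted p = 0.00795 and had 0.142 with estimated correlation. Glycolysis genes rose in 12 of 20 cases and fell in 2 (same over the list alone; camera adjusted p = 0.01, and 0.631 with estimated correlation).

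Immediate early genes rose in 7 of 13 cases and fell in 2 (same over the list alone), FOSB by 9.37-fold and NR4A1 by 7.42-fold (camera adjusted p = 0.0294, and 0.631 with estimated correlation), a list call ended by 5 alternatives. Ribosomal protein genes fell in 16 of 24 cases and 1 rose (19 and 2 over the list alone; camera adjusted p = 0.0136, and 0.631 with estimated correlation), and median-of-ratios scaling or scaling to nuclear genes ended this call. Hypoxia genes did not pass as a list (9 of 19 rose and 4 fell over all genes and over the list alone; adjusted p = 0.0555), with ANKRD37 6.25-fold, ANGPTL4 4.65-fold and NDRG1 2.6-fold higher. Type I interferon genes did not pass either (7 of 19 rose and 8 fell over all genes and over the list alone; adjusted p = 0.515; median -0.36, mean 0.24), with OAS1 7.93-fold and IFI6 4.65-fold higher. Among mesenchymal genes 5 of 15 rose and 6 fell over all genes and over the list alone (adjusted p = 0.628), S100A4 by 7.09-fold upward and the receptor kinase gene AXL by 2.59-fold downward.

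limma called 7635 of 14557 genes, 3136 higher and 4499 lower under the skin, of which 1183 changed at least 2-fold. The balance turned with scaling, to 3905 higher and 3603 lower with median-of-ratios scaling and 4158 higher and 3296 lower with scaling to nuclear genes.

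The fourth comparison set metastases of forebrain against metastases of hindbrain (n = 3 each). POSTN (ENSG00000133110.14, chromosome 13, 37562583 to 37598844) was 4.53-fold higher in forebrain (19.4 ± 5.24 against 3.44 ± 0.566), AXIN2 2.22-fold higher (57 ± 9.82 against 25 ± 3.25) and SH3GL3, an endophilin gene, 2.33-fold higher (18.7 ± 4.3 against 7.46 ± 1.95). The adhesion genes CEACAM6 (ENSG00000086548.8, chromosome 19, 41750977 to 41772211) and CEACAM1 were 4.05-fold (1.86 ± 0.845 against 10.7 ± 4.49) and 2.56-fold lower in forebrain (1.695 ± 0.651 against 5.77 ± 0.544), and HP was 2.66-fold lower (79 ± 8.2 against 212 ± 22.9). These 6 genes were called in every alternative.

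CDH1 was at 67.7 ± 6.99 in forebrain and 67.5 ± 5.97 in hindbrain. Levels of EPCAM (22.25 ± 4.82 against 33.25 ± 8.65; adjusted p = 0.0894), ZEB1 (17.2 ± 2.64 against 16.2 ± 1.08), MKI67 (71.5 ± 2.89 against 68.2 ± 15.1), TUBB3 (4.70 ± 1.58 against 4.88 ± 1.76), L1CAM (71 ± 11.1 against 67.3 ± 5.1) and SNAP25 (5.12 ± 2.15 against 3.27 ± 0.736) did not pass the test. EPCAM passed with the pairing (adjusted p = 0.00359) and without hindbrain metastasis replicate 2 (0.0212; 0.00359 to 0.363 over its alternatives). DPYSL3, a gene of neurite growth, was 2.16-fold higher and the transcription factor gene ARNT2 2.73-fold lower in forebrain, but neither passed when only these 6 libraries were fitted. S100A8 (2.75-fold lower) and the clock gene NPAS2 (2.7-fold lower) did not pass with voom. Calls of COL1A2 (3.5-fold), STRA6 (2.19-fold), LINC00173 (2.17-fold), NKD1 (2.15-fold), FN1 (2.16-fold), SOX2 (2.1-fold), SLC2A1 (1.5-fold) and VIM (1.23-fold), higher in forebrain, were lost in at least 2 alternatives. So were those of CXCL8 (2.38-fold), TIMP1 (1.51-fold), B2M (1.28-fold), FDPS (1.27-fold) and SREBF2 (1.19-fold), lower in forebrain. NCAM1 (1.71-fold higher) was lost with library weights.

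Cholesterol synthesis genes fell in forebrain metastases in 3 of 21 cases (12 adjusted over the list alone; camera adjusted p = 3.58e-08, and 0.355 with estimated correlation). Mesenchymal genes rose in 3 of 15 cases (4 over the list alone; camera adjusted p = 0.0105, and 0.142 with estimated correlation), a call lost without forebrain metastasis replicate 3 or without cross-species genes. None of the other 20 human lists passed.

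limma called 481 of 14557 genes, 270 higher and 211 lower in forebrain, and 1026 with libraries of equal number treated as pairs. The balance turned with median-of-ratios scaling (225 higher and 262 lower), quantile normalization (211 and 245) and nuclear genes (247 and 248). The count was 39 with only these 6 libraries fitted, 58 with library weights, 100 with voom and 204 without the filter on low values. It was 247 without cross-species genes, 297 without forebrain metastasis replicate 2 and 735 without forebrain metastasis replicate 3. In simulated data of this design 86 of 257 calls were false, against 11 of 159 with only these 6 libraries.

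The fifth comparison set the host forebrain with tumour (n = 3) against tumour-free forebrain (n = 4). Gfap, the astrocyte filament gene that marks reactive gliosis, was 4.86-fold higher with tumour (736 ± 181 against 149 ± 28.2), and the complement gene C4b was 6.13-fold higher (331 ± 37.7 against 53.65 ± 10). The chemokine gene Ccl12 was 7.93-fold higher (14.5 ± 0.542 against 1.05 ± 0.666) and Aif1, a microglia and macrophage marker, 2.9-fold higher (26.5 ± 5.91 against 8.37 ± 0.844). Pmch, the precursor of the hypothalamic peptide melanin-concentrating hormone, was 45.6-fold lower (0.444 ± 0.236 against 64.8 ± 9.19). Hcrt, the orexin precursor of the lateral hypothalamus, had 0 of 189342826 reads with tumour and 432 of 76998897 reads in tumour-free forebrain, at least 354-fold lower against a floor of 3 reads over the group.

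The inhibitory receptor gene Lag3 (7.35-fold), the nuclear non-coding RNA Malat1 (4.85-fold; 5007 ± 387 against 1050 ± 232), the adaptor gene Fyb (4.84-fold), the integrin gene Itgax (4.81-fold), Ifi44 (4.75-fold), Cd180 (4.31-fold) and Aspg (4.28-fold) were also higher with tumour. The vasopressin gene Avp (11.7-fold; 3.62 ± 2.67 against 49.2 ± 20), the thalamic transcription factor gene Shox2 (6.73-fold), Capn11 (4.08-fold), the glutamate transporter gene Slc17a6 (3.51-fold; 21.7 ± 7.36 against 76.7 ± 11.7), Rab37 (3.34-fold) and the oxytocin gene Oxt (3.32-fold) were lower; the Oxt call was lost when only these 7 libraries were fitted. Cd68, a lysosomal marker of phagocytes, rose 2.29-fold, and the microglial genes Tmem119 and P2ry12 rose 2.05-fold (60.5 ± 11.3 against 28.7 ± 2.79) and 1.71-fold. The neuronal nuclear gene Rbfox3 (245 ± 19 against 251.5 ± 17.3), the myelin gene Mbp (1614 ± 223 against 1598 ± 211), the endothelial junction gene Cldn5 (18.6 ± 6.74 against 11.9 ± 2.15) and H2-K1 (39.9 ± 10.3 against 23.6 ± 6.77; adjusted p = 0.0731) did not pass. Neither did Cd74 (6.65 ± 0.745 against 4.95 ± 1.73) and the hindbrain factor gene En2 (0.248 ± 0.0495 against 0.374 ± 0.165). H2-K1 passed with the replicate number as a block (adjusted p = 0.00294), with library weights (0.02) and without tumour-free forebrain replicate 1 (0.0489) or forebrain metastasis replicate 3 (0.0388; 0.00294 to 0.249 over its alternatives). Cldn5 passed with that block alone (0.0474; 0.0474 to 0.502 over its alternatives).

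Reactive astrocyte genes rose in 13 of 16 cases (14 over the list alone), with Cxcl10 3.91-fold and the cytokine receptor gene Osmr 3.41-fold higher. The reactive astrocyte list passed camera with adjusted p = 2.83e-12 and had 0.0341 with estimated correlation. Type I interferon genes rose in 19 of 21 cases (20 over the list alone), with Usp18 3.97-fold, Ifi27l2a 3.7-fold and Irf7 3.48-fold higher. The interferon list passed camera with adjusted p = 7.61e-17 and had 0.0253 with estimated correlation. Complement genes rose in 12 of 13 cases (same over the list alone), with C1qc 4.27-fold and C1qb 3.79-fold higher. The complement list passed camera with adjusted p = 1.48e-13 and had 0.0325 with estimated correlation. Of 12 chemokine and cytokine genes, 11 rose and 1 fell (same over the list alone), Il1b by 3.09-fold upward. The cytokine list passed camera with adjusted p = 7.06e-10 and had 0.0152 with estimated correlation.

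Homeostatic microglia genes rose in 14 of 15 cases (15 over the list alone), with Fcrls 3.75-fold, Olfml3 2.67-fold and the fractalkine receptor gene Cx3cr1 2.43-fold higher. The homeostatic microglia list passed camera with adjusted p = 4.91e-12 and had 0.0886 with estimated correlation. Activated microglia and phagocyte genes rose in 15 of 20 cases (same over the list alone), Clec7a by 3.39-fold. The activated microglia list passed camera with adjusted p = 7.06e-10 and had 0.0886 with estimated correlation. Monocyte and macrophage genes rose in 7 of 14 cases (same over the list alone), with the integrin gene Itgam 4.33-fold and Ms4a6c 2.61-fold higher. The monocyte list passed camera with adjusted p = 2.95e-05 and had 0.236 with estimated correlation. Proliferation genes rose in 16 of 21 cases (19 over the list alone), Top2a by 3.56-fold and Mki67 by 2.69-fold. The proliferation list passed camera with adjusted p = 1.14e-11 and had 0.0779 with estimated correlation. Astrocyte genes rose in 6 of 15 cases (same over the list alone), the water channel gene Aqp4 by 1.9-fold. The astrocyte list passed camera with adjusted p = 0.00223 and had 0.449 with estimated correlation. Fibroblast and collagen genes rose in 8 of 16 cases and 1 fell (same over the list alone), Col4a1 by 3.37-fold upward. The fibroblast list passed camera with adjusted p = 0.00191 and had 0.449 with estimated correlation. MHC class I genes rose in 6 of 14 cases (7 over the list alone) and 1 fell, B2m by 1.83-fold upward. The MHC class I list passed camera with adjusted p = 0.00971 and had 0.482 with estimated correlation. Endothelial genes rose in 7 of 19 cases (8 over the list alone) and 1 fell (camera adjusted p = 0.0144, and 0.612 with estimated correlation). Oligodendrocyte precursor genes rose in 4 of 12 (same over the list alone; camera adjusted p = 0.0226, and 0.449 with estimated correlation). Both calls were lost without forebrain metastasis replicate 2. Leaving out cross-species genes ended the calls of astrocyte, precursor, monocyte and MHC class I genes.

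Oxidative phosphorylation genes fell in 23 of 25 cases (24 over the list alone), the cytochrome c oxidase gene Cox5a by 1.48-fold. The oxidative phosphorylation list passed camera with adjusted p = 1.27e-10 and had 0.318 with estimated correlation. Cholesterol synthesis genes fell in 16 of 20 cases (18 over the list alone), with Insig1 1.86-fold and Nsdhl 1.74-fold lower. The cholesterol list passed camera with adjusted p = 4.92e-09 and had 0.14 with estimated correlation. Neuronal genes fell in 13 of 25 cases and rose in 2 (same over the list alone), with Tubb3 1.73-fold and Stmn3 1.53-fold lower. The neuronal list passed camera with adjusted p = 0.00124 and had 0.449 with estimated correlation. Lists that did not pass were glutamatergic neurons (0 of 15 rose and 3 fell, 0 and 2 over the list alone; adjusted p = 0.883), GABAergic neurons (0 of 15 rose and 3 fell, 0 and 2 over the list alone; adjusted p = 0.563) and oligodendrocytes (2 of 18 rose, 0 over the list alone; adjusted p = 0.326). MHC class II genes did not pass (2 of 7 rose, same over the list alone; adjusted p = 0.0577), with the protease gene Ctss 3.2-fold higher. The medians of glutamatergic and GABAergic genes, 0.11 and 0.02, differed in sign from their means, -0.07 and -0.14. The numbers over all genes and over the list alone were also equal for pericytes and smooth muscle (4 of 13 rose; adjusted p = 0.0628), neutrophils (2 rose and 1 fell of 7; adjusted p = 0.52) and hypoxia (3 rose and 2 fell of 18; adjusted p = 0.469; median -0.01, mean 0.05). They were equal, too, for mitochondrially encoded genes (2 of 7 rose; adjusted p = 0.134), choroid plexus and ependyma (0 of 14; adjusted p = 0.141), erythroid genes (1 fell of 7; adjusted p = 0.0526) and hindbrain regional genes (1 fell of 25; adjusted p = 0.563). Immediate early genes (1 of 16 rose, same over the list alone; adjusted p = 0.864), lymphocytes (2 of 3 rose; 2 rose and 1 fell over the list alone; adjusted p = 0.289) and forebrain regional genes (3 rose and 1 fell of 18; 3 and 0 over the list alone; adjusted p = 0.205) did not pass either.

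limma called 4793 of 15777 genes, 2265 higher and 2528 lower with tumour, of which 322 changed at least 2-fold. The balance turned with median-of-ratios scaling (2654 higher and 2096 lower), nuclear genes (2471 and 2303), no filter on low values (2435 and 2014) and without tumour-free forebrain replicate 3 (1927 and 1895). It was near even with the replicate number as a block (1878 and 1875) and without forebrain metastasis replicate 2 (2353 calls, 1183 and 1170). The count was 2695 without cross-species genes.

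**Figure D3:**
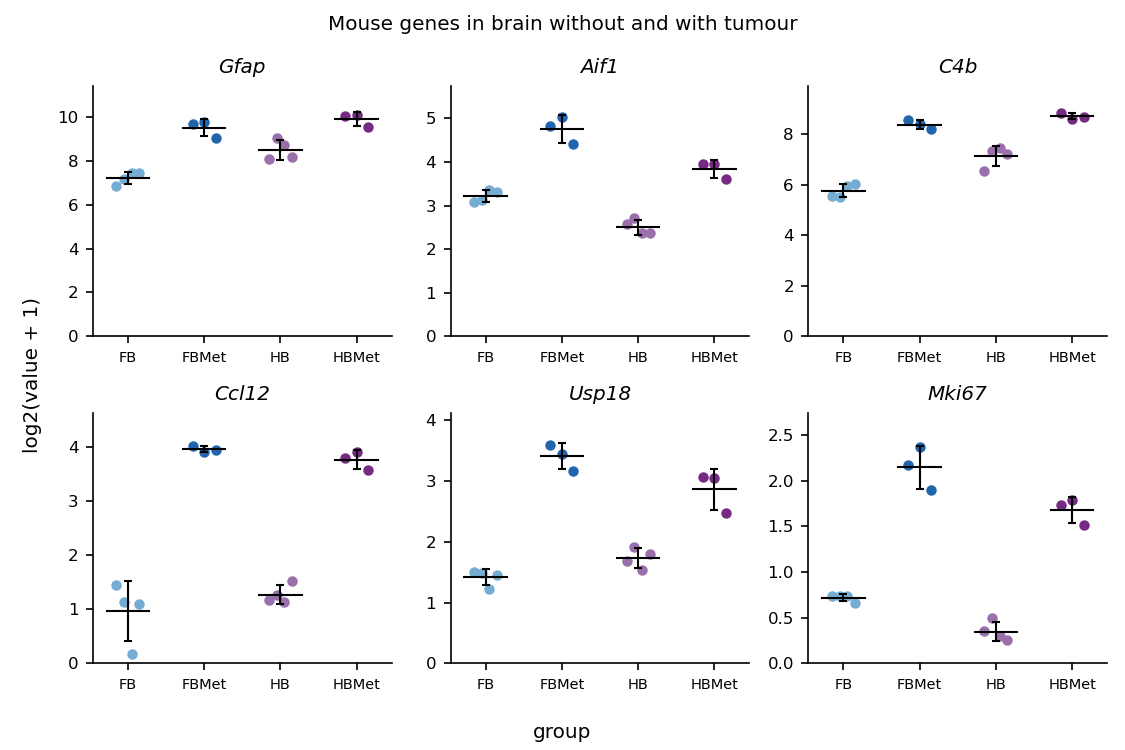
Mouse genes in log2(value + 1), where value is rescaled RPKM, in tumour-free forebrain (FB, n = 4), forebrain with metastases (FBMet, n = 3), tumour-free hindbrain (HB, n = 4) and hindbrain with metastases (HBMet, n = 3). Points are libraries, lines are means and bars are SD; Gfap averaged 736 against 149 in forebrain and 962.5 against 371 in hindbrain.

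The sixth comparison set the host hindbrain with tumour (n = 3) against tumour-free hindbrain (n = 4). Ccl12 was 5.63-fold higher with tumour (12.6 ± 1.58 against 1.42 ± 0.306) and Itgax 4.96-fold higher (5.62 ± 0.827 against 0.334 ± 0.136). Socs3, a feedback inhibitor of cytokine signalling, was 4.66-fold higher (26.6 ± 8.86 against 4.76 ± 0.928) and Gpnmb, a phagocyte glycoprotein gene, 4.21-fold higher (7.11 ± 1.74 against 0.901 ± 0.203). Gfap was 2.65-fold higher (962.5 ± 189 against 371 ± 120). The calpain gene Capn11 was 4.44-fold lower (1.42 ± 0.75 against 9.52 ± 1.65).

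The transporter gene Slc43a3 (4.73-fold), Lag3 (4.42-fold), Cd52 (4.35-fold) and Clec7a (4.34-fold) were also higher, and the endothelin gene Edn3 1.51-fold lower. Aif1 rose 2.52-fold (13.4 ± 1.87 against 4.70 ± 0.682) and Cd68 2.74-fold. Calls of Vipr1 (1.61-fold), Lzts1 (1.55-fold), Rab40b (1.49-fold), Epha4 (1.47-fold), Camk2n1 (1.46-fold) and Fam212b (1.38-fold), lower with tumour, were lost in 2 or more alternatives. Tmem119 rose 1.77-fold, a call lost without hindbrain metastasis replicate 1 (adjusted p = 0.06) or 2 (0.0629; 0.000847 to 0.0629 over its alternatives). P2ry12 (25.3 ± 6.2 against 16.9 ± 4.51; adjusted p = 0.164), Cd74 (14.7 ± 1.49 against 9.805 ± 4.74), Cldn5 (17.4 ± 3.13 against 11.9 ± 4.8) and H2-K1 (49.9 ± 10.3 against 34.75 ± 12.6) did not pass. Neither did Mbp (3916 ± 474 against 3759 ± 416), Rbfox3 (167 ± 10.5 against 183 ± 22.3) and En2 (18.9 ± 4.27 against 15.8 ± 6.63), but P2ry12 passed with library weights (adjusted p = 0.0459) and without tumour-free hindbrain replicate 3 (0.0292; 0.0292 to 0.711 over its alternatives). H2-K1 passed with the replicate number as a block (adjusted p = 0.048; 0.048 to 0.908 over its alternatives).

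Complement genes rose in 10 of 13 cases (11 over the list alone), with C1qc 4.17-fold, C1qb 4.03-fold and C4b 2.97-fold higher. The complement list passed camera with adjusted p = 6e-25 and had 0.00385 with estimated correlation. Reactive astrocyte genes rose in 13 of 16 cases (14 over the list alone), the lipocalin gene Lcn2 by 3.65-fold and Timp1 by 3.33-fold. The reactive astrocyte list passed camera with adjusted p = 1.52e-24 and had 0.00385 with estimated correlation. Activated microglia and phagocyte genes rose in 10 of 20 cases (17 rose and 1 fell over the list alone; camera adjusted p = 2.83e-22, and 0.012 with estimated correlation). Chemokine and cytokine genes rose in 11 of 12 cases (same over the list alone), Il1b by 3.07-fold. The cytokine list passed camera with adjusted p = 4.77e-20 and had 0.000673 with estimated correlation. Proliferation genes rose in 10 of 21 cases (17 over the list alone), Top2a by 4.84-fold (camera adjusted p = 8.41e-19, and 0.0153 with estimated correlation). Homeostatic microglia genes rose in 10 of 15 cases (12 over the list alone), Fcrls by 2.89-fold. The homeostatic microglia list passed camera with adjusted p = 1.49e-16 and had 0.0302 with estimated correlation. Type I interferon genes rose in 9 of 21 cases (13 over the list alone), Ifi27l2a by 2.79-fold and Ifi44 by 2.72-fold. The interferon list passed camera with adjusted p = 4.3e-15 and had 0.0153 with estimated correlation. Monocyte and macrophage genes rose in 7 of 14 cases (8 over the list alone), Ms4a6c by 3-fold and the endotoxin co-receptor gene Cd14 by 2.36-fold. The monocyte list passed camera with adjusted p = 1.28e-12 and had 0.0302 with estimated correlation.

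Cholesterol synthesis genes fell in 2 of 20 cases (13 over the list alone; camera adjusted p = 3.05e-08, and 0.125 with estimated correlation). Neuronal genes as a list fell, with 0 of 25 members called (7 over the list alone; camera adjusted p = 2.84e-07, and 0.149 with estimated correlation). So did glutamatergic neuron genes (0 of 15, 5 over the list alone; camera adjusted p = 7.12e-05, and 0.0857 with estimated correlation) and forebrain regional genes (0 of 18, 8 over the list alone; camera adjusted p = 8.98e-06, and 0.211 with estimated correlation). In 2 forebrain genes, chosen here after their values were seen, tumour-free hindbrain libraries also differed: Ddn was 1.59 in replicate 1 and 25.7 to 38.1 in the others, and Tbr1 0.404 against 6.51 to 13.4, with Ddn at 1.90 to 2.42 in hindbrain with tumour. MHC class II genes rose in 1 of 7 cases (2 over the list alone; camera adjusted p = 0.000127, and 0.0857 with estimated correlation), Ctss by 3.08-fold. Leaving out cross-species genes ended the calls of neuronal and glutamatergic genes. Oxidative phosphorylation genes fell as a list with 0 of 25 members called over all genes and over the list alone (camera adjusted p = 0.00401, and 0.711 with estimated correlation), a call lost with the replicate number as a block (adjusted p = 0.0729). Erythroid genes fell as a list (0 of 7, 1 over the list alone; camera adjusted p = 0.0127, and 0.406 with estimated correlation). Hypoxia genes rose as a list (0 of 18, same over the list alone; camera adjusted p = 0.0187, and 0.211 with estimated correlation), and so did neutrophil genes (2 of 7, same over the list alone; camera adjusted p = 0.0252, and 0.227 with estimated correlation). GABAergic genes fell as a list (0 of 15, same over the list alone; camera adjusted p = 0.0388, and 0.227 with estimated correlation). Endothelial genes rose as a list (0 of 19, same over the list alone; camera adjusted p = 0.0461, and 0.742 with estimated correlation), a call lost with the replicate number as a block (adjusted p = 0.0729). The GABAergic and endothelial calls were ended by 8 and 9 of 19 alternatives. Between 1 and 9 alternatives ended each of these 5 calls.

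limma called 512 of 15777 genes, 460 higher and 52 lower with tumour, of which 160 changed at least 2-fold. Lower calls were 273 without tumour-free hindbrain replicate 1, 194 with library weights, 9 without hindbrain metastasis replicate 2 and 8 with only the groups compared, while higher calls outnumbered them in every alternative. The count was 294 with a stricter filter, 336 without cross-species genes and 824 with library weights. It was 804 without tumour-free hindbrain replicate 1, and 324 and 291 without hindbrain metastasis replicates 1 and 2.

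**Figure D4:**
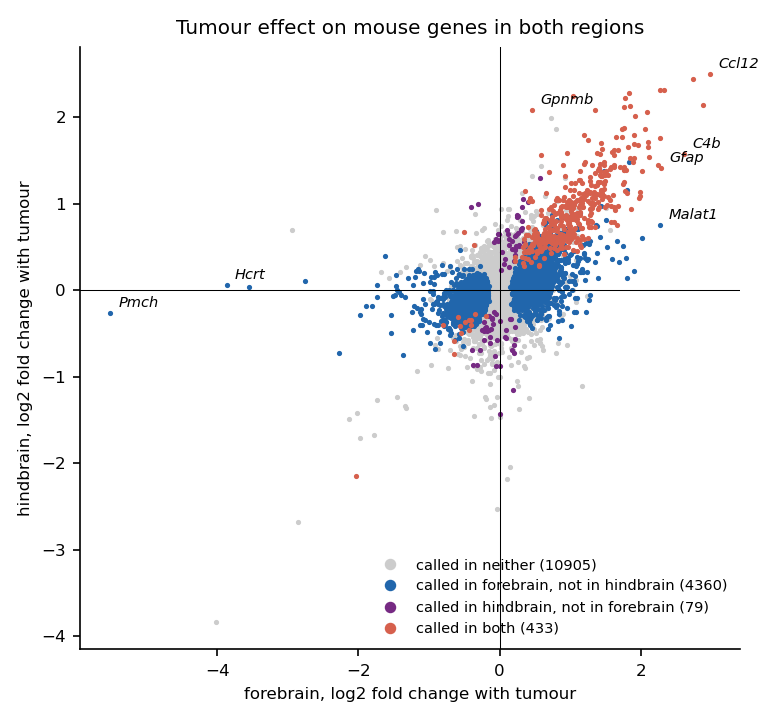
Log2 fold change with tumour in forebrain (x axis) and hindbrain (y axis) for each of the 15777 mouse genes tested. Colours give the limma calls: 433 genes in both regions (2 of them in opposite directions), 4360 in forebrain and not in hindbrain, 79 in hindbrain and not in forebrain, and 10905 in neither; the difference itself passed for 72 genes.

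The seventh comparison tested whether the tumour effect differed between forebrain and hindbrain. Pmch had log2 changes with tumour of -5.51 in forebrain and -0.27 in hindbrain that differed by -5.24 ± 0.2 (SE; adjusted p = 3.1e-09). Hcrt had log2 changes of -3.87 and 0.06 (difference -3.93 ± 0.16; adjusted p = 4e-09). Tumour-free hindbrain held little of either transcript (0.749 to 1.54 for Pmch and 0 to 0.128 for Hcrt), so a like fall could not be seen there, and these differences restate the fall in forebrain. Gpnmb rose more in hindbrain, with log2 changes of 0.46 in forebrain and 2.07 in hindbrain (difference -1.61 ± 0.2; adjusted p = 0.00431). These 3 genes were called in every alternative.

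Avp (difference -3.59), Irx2 (-1.71), Rab37 (-1.66), Slc17a6 (-1.63), the calcium-binding protein gene Calb2 (-1.51), the angiotensinogen gene Agt (-1.46), the proteoglycan gene Dcn (-1.4) and S1pr3 (-0.63) also had lower log2 changes in forebrain. The protease inhibitor gene A2m (1.42), Col6a1 (1.43), Tfcp2l1 (1.34), the axon guidance receptor gene Robo3 (1.12), Trank1 (1.08), Ftx (0.94), Cxcl10 (0.9), Ryr3 (0.89), Gli3 (0.82) and Adcy5 (0.8) had higher ones. All 18 of these calls were lost in at least 2 alternatives or on leaving out single libraries. The limit stated for Pmch applies to Avp, at 0.204 to 0.547 in tumour-free hindbrain. The difference did not pass for Gfap (0.87; adjusted p = 0.198), Aif1 (0.2; adjusted p = 0.62), Cd68 (-0.26; adjusted p = 0.572), P2ry12 (0.22; adjusted p = 0.689) or Tmem119 (0.21; adjusted p = 0.646).

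Type I interferon genes rose more in forebrain as a list, with 0 of 21 members called over all genes and 13 over the list alone (median difference 0.54; camera adjusted p = 2.15e-10, and 0.226 with estimated correlation). Oxidative phosphorylation genes fell more in forebrain as a list, with 0 of 25 called and 13 over the list alone (median difference -0.3; camera adjusted p = 1.22e-08, and 0.779 with estimated correlation). As lists, forebrain regional genes differed upward (0 of 18, 5 over the list alone; camera adjusted p = 1.15e-05, and 0.779 with estimated correlation) and cholesterol synthesis genes downward (0 of 20 over all genes and over the list alone; camera adjusted p = 0.00227, and 0.779 with estimated correlation). Fibroblast and collagen genes (1 higher and 1 lower of 16, 4 and 1 over the list alone; camera adjusted p = 0.00304, and 0.779 with estimated correlation) and astrocyte genes (0 of 15, 3 higher over the list alone; 0.00655, and 0.786 with estimated correlation) differed upward. So did oligodendrocyte precursor genes (0 of 12, 4 higher over the list alone; 0.0107, and 0.779) and homeostatic microglia genes (0 of 15, same over the list alone; 0.0107, and 0.82). Glutamatergic genes also differed upward (1 lower of 15, 2 higher and 1 lower over the list alone; 0.0312, and 0.779 with estimated correlation; 0.0642 with the pairing), and choroid plexus genes downward (0 of 14, same over the list alone; 0.00665, and 0.82 with estimated correlation). The choroid plexus call was lost without forebrain metastasis replicate 2 or 3, the astrocyte call without replicate 2, and the homeostatic microglia call without replicate 2 or hindbrain metastasis replicate 3. The fibroblast call was lost without hindbrain metastasis replicate 1. Leaving out cross-species genes ended the calls of astrocyte, precursor, homeostatic microglia and glutamatergic genes, and 8 of 26 alternatives ended the last. Complement genes (0 of 13, 1 over the list alone; adjusted p = 0.156), reactive astrocyte genes (1 higher and 1 lower of 16, same over the list alone; adjusted p = 0.485) and activated microglia genes (1 lower of 20, 2 over the list alone; adjusted p = 0.559) did not pass.

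limma called 72 of 15777 genes, 40 with a higher and 32 with a lower change in forebrain. Pairing by number, with tumour-free libraries included, gave 50, and the balance turned (20 higher and 30 lower). The count was 30 without the filter on low values (13 higher and 17 lower), 43 without cross-species genes (20 higher and 23 lower), 113 with median-of-ratios scaling (78 higher and 35 lower), 129 with quantile normalization and 173 with voom. It was 660 with library weights and 631 without the first tumour-free library of each region. Leaving out any single one of the 14 libraries gave between 12 (1 higher and 11 lower) and 343 (246 and 97).

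**Figure D5:**
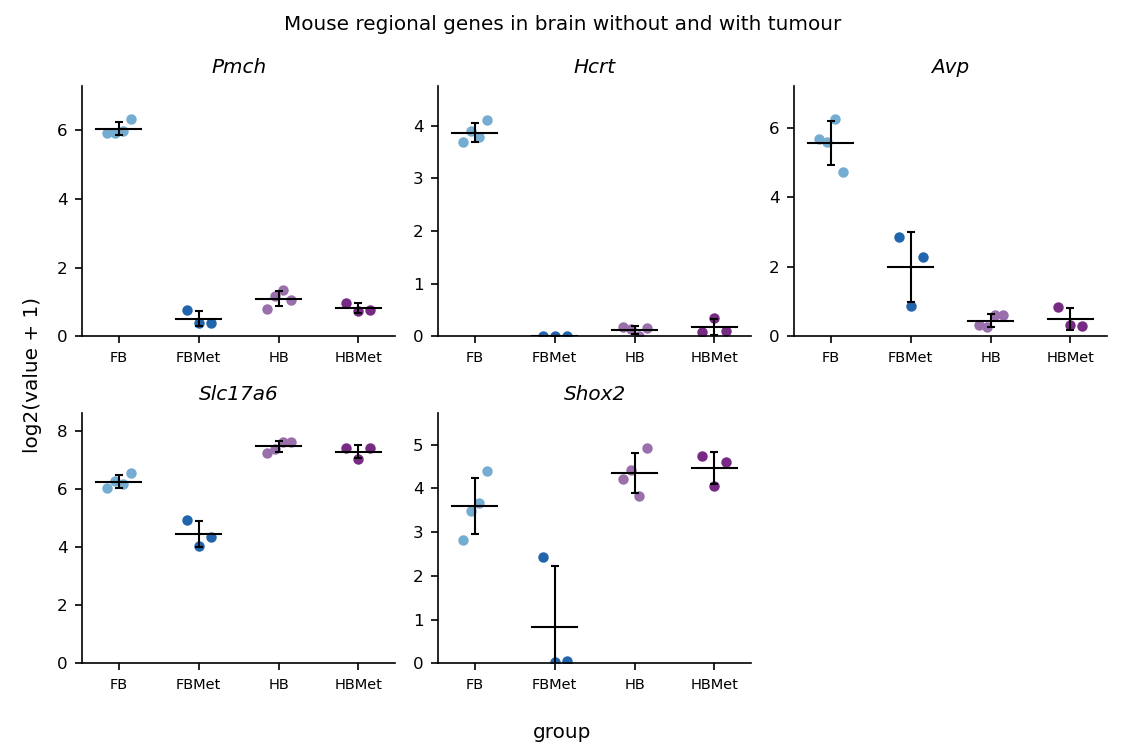
Mouse regional genes in log2(value + 1), where value is rescaled RPKM, in tumour-free forebrain (FB, n = 4), forebrain with metastases (FBMet, n = 3), tumour-free hindbrain (HB, n = 4) and hindbrain with metastases (HBMet, n = 3). Points are libraries, lines are means and bars are SD; Pmch averaged 64.8 in FB and 0.444 in FBMet.

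The eighth comparison set tumour-free forebrain against tumour-free hindbrain (n = 4 each), which checks the region labels. The cerebellar genes Pcp2 (203-fold; 0.196 ± 0.119 against 261 ± 118), Cbln3 (137-fold) and Gabra6 (99.5-fold) and the glycine transporter gene Slc6a5 (70.7-fold) were lower in forebrain. Avp (34.3-fold), Pmch (30.5-fold), the dendritic gene Ddn (24.8-fold; 441 ± 37.1 against 25.2 ± 16.6), Oxt (23.7-fold) and the striatal adenosine receptor gene Adora2a (19.6-fold) were higher. En2 was 11.6-fold lower in forebrain.

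Dlx1 (16.3-fold), the potassium channel gene Kcnj4 (16.2-fold) and the cortical factor gene Tbr1 (16-fold) were also higher in forebrain, and Cnpy1 (57.8-fold), Ppp1r17 (28.7-fold), Arhgef33 (22-fold) and the Purkinje cell gene Car8 (21.6-fold) lower. Forebrain regional genes were higher in 17 of 18 cases (same over the list alone; camera adjusted p = 2.11e-14, and 0.107 with estimated correlation). All 25 hindbrain regional genes were lower (same over the list alone; camera adjusted p = 5.16e-18, and 0.0292 with estimated correlation). Glutamatergic neuron genes were higher in 12 of 15 cases and lower in 1 (same over the list alone), with Nrgn 9.73-fold and Camk2a 7.54-fold higher. The glutamatergic list passed camera with adjusted p = 3.74e-07 and had 0.107 with estimated correlation. Oligodendrocyte genes were lower in 17 of 18 cases (18 over the list alone), with Mbp 2.36-fold lower. The oligodendrocyte list passed camera with adjusted p = 2.21e-07 and had 0.455 with estimated correlation. Astrocyte genes were lower in 11 of 15 cases and higher in 1 (same over the list alone), S100b by 3.45-fold downward (camera adjusted p = 0.00249, and 0.855 with estimated correlation). Homeostatic microglia genes were higher in 11 of 15 (12 over the list alone), P2ry12 by 1.73-fold (camera adjusted p = 0.000411, and 0.758 with estimated correlation). Gfap was 2.41-fold lower in forebrain, the complement gene C3 6.49-fold lower, the osteopontin gene Spp1 5.99-fold lower and the neurofilament gene Nefh 5.13-fold lower. GABAergic genes were higher in 8 of 15 cases and lower in 4 (same over the list alone; camera adjusted p = 0.0216, and 0.455 with estimated correlation), a call lost with quantile normalization, a pseudocount of 0.1 or voom. Immediate early genes were higher in 6 of 16 (same over the list alone; 0.0221, and 0.933), a call lost without tumour-free hindbrain replicate 1. Cholesterol synthesis genes were lower in 13 of 20 (1 higher and 13 lower over the list alone; 0.0248, and 0.855), a call lost without tumour-free hindbrain replicate 3.

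limma called 8327 of 15777 genes, 3194 higher and 5133 lower in forebrain, of which 1367 changed at least 2-fold. Median-of-ratios scaling gave 4012 higher and 4242 lower and quantile normalization 3925 and 4201, while leaving out the first library of each region gave 7437 calls.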

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

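Of the tests in this part, those of a piece of tissue and of gene length were written before their results were seen, and all others were chosen after.

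The tumour effect on 72 mouse genes differed between forebrain and hindbrain in the test of the difference itself. Log2 changes were lower in forebrain for Pmch (difference -5.24), Hcrt (-3.93), Avp (-3.59), Irx2 (-1.71), Rab37 (-1.66), Slc17a6 (-1.63), Gpnmb (-1.61), Calb2 (-1.51), Agt (-1.46), Dcn (-1.4) and S1pr3 (-0.63). They were higher in forebrain for Col6a1 (1.43), A2m (1.42), Tfcp2l1 (1.34), Robo3 (1.12), Trank1 (1.08), Ftx (0.94), Cxcl10 (0.9), Ryr3 (0.89), Gli3 (0.82) and Adcy5 (0.8). Tumour-free hindbrain held little Pmch (0.749 to 1.54), Hcrt (0 to 0.128) and Avp (0.204 to 0.547), so their differences restate the fall in forebrain and do not show that the tumour acts differently by region. In other splits, libraries of equal number and state moved together and the tumour effect common to both regions was taken out. Of these 35 splits, 2 gave as many calls, counting the real one, so this test does not exclude chance for this count. The highest other split gave 515 calls, many times the real count, and set tumour-free replicates 2, 3 and 4 of both regions against all other libraries. This points to a structure of the samples in which tumour-free replicate 1 stands apart from the other tumour-free libraries. Splits made first, within each region, carry the tumour effect itself (3138 calls in the highest; 2 of 100 as large) and do not test the difference.

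Pmch, Hcrt, Avp, Shox2 and Slc17a6, transcripts of hypothalamus or thalamus, were lower in tumour-bearing forebrain. Fewer reads are excluded, since tumour-bearing forebrain held 3.28 times the mouse reads of tumour-free forebrain. Further hypothalamus and thalamus genes had a median log2 change of -0.59 (95% interval -0.804 to -0.314; 22 tested, 16 called lower and 0 higher), and telencephalic regional genes one of 0.154, so a piece of tissue with less hypothalamus and thalamus is a candidate explanation. Loss of these neurons in tumour-bearing animals stays open, because labels of 0 libraries state whether these parts were included. Both explanations predict fewer such transcripts and cannot be told apart with these data.

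Human neuronal, synaptic and host marker genes called higher in brain metastases than under the skin fall into 2 parts. For the 6 with means under 1 in the monolayer and under the skin, the median share of metastasis reads expected from mouse RNA was 73% (24.3 to 122%), so misassigned mouse reads are a candidate source of most of these transcripts. CDH5 goes the other way, with 0 of its 105 metastasis reads expected from mouse RNA. For the 8 also seen outside brain the median share was 0.482% (0 to 4.46%), which excludes that source as the main one. No biological explanation was tested for these 8.

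Oxidative phosphorylation genes were lower in tumour-bearing forebrain, with a median log2 change of -0.401 (-0.449 to -0.375). With the trend on gene length taken out the median was -0.386 (-0.461 to -0.364), which excludes gene length as the whole cause. In tumour-bearing hindbrain, whose libraries share the greater depth, the median was -0.108 (-0.125 to -0.0815). As for every tumour effect, library set or depth could add to the change and cannot be told apart from the tumour.

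Other splits of the libraries tested the remaining counts. In brain against subcutaneous tumours chance can be excluded, with 7276 calls and 1 of 100 splits as large (highest other 3296). So it did with brain metastases as 1 group and those of equal number moved together (6847, 1 of 35, highest other 4887). Brain against monolayer gave 6247 calls (1 of 84; highest other 2754), which excludes chance only if the 6 metastases are independent; moved together, they give 10 splits, too few for a share under 0.05 (5797 calls; highest other 0). Chance can be excluded in subcutaneous tumours against monolayer (7635; 1 of 35; highest other 4756), tumour in forebrain (4793; 1 of 35; highest other 2734), tumour in hindbrain (512; 1 of 35; highest other 385) and tumour-free forebrain against hindbrain (8327; 1 of 35; highest other 7). In both tumour comparisons the highest other split set tumour-free replicates 2, 3 and 4 against the rest. For forebrain against hindbrain metastases, 1 of 10 splits was as large, and 10 are too few for a share under 0.05 (481 calls; highest other 90).

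Of 384 sets of 4 libraries tested, 38 had 1 library far from the others, where chance gives about 1 in 20. Under the skin, human values stood apart (other libraries in parentheses) in replicate 1 for CEACAM1 at 19.4 (17.5 to 17.6), IRF9 at 11.4 (18.2 to 19.6), SNED1 at 28.4 (42.1 to 44.5) and UBASH3B at 10.3 (7.5 to 7.93). They did in replicate 2 for CCL2 at 468 (96.3 to 120), MUC1 at 284 (136 to 153), CDH2 at 0.846 (0.449 to 0.479), CNTN1 at 0.143 (0.377 to 0.413), DHCR7 at 58.5 (70.2 to 72.5), SREBF2 at 109 (125 to 127) and MSC-AS1 at 3.99 (2.35 to 2.53). In replicate 3, CEACAM6 was at 1.95 (0.96 to 1.03), GAP43 at 0.0219 and GRIA3 at 0.021 (0 in the others).

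In tumour-free forebrain, replicate 1 stood apart in Fos at 19.4 (82.5 to 91.4) and P2ry12 at 37.2 (26.6 to 27.8), and replicate 2 in C3 at 1.25 (2.9 to 3.12) and in the share of mouse reads at 99.97%. Replicate 3 did in Pcp2 at 0.373 (0.125 to 0.145) and Tmem119 at 32.9 (26.9 to 27.7), and replicate 4 in Pmch at 78.5 (59.6 to 61.2), Mki67 at 0.577 (0.662 to 0.673) and Osmr at 1.21 (1.56 to 1.63). In tumour-free hindbrain, Fos was at 14.7 in replicate 1 (85.6 to 97.1). Replicate 2 stood apart in C1qc at 31.8 (19.4 to 20.2), Col4a1 at 65.9 (45.7 to 48.7), Lcn2 at 5.83 (1.4 to 1.7), Olfml3 at 9.26 (4.91 to 5.64), Itgax at 0.535 (0.239 to 0.287) and Ccl8 at 0.115 (0 in the others). Replicate 3 did in Nefh at 246 (191 to 200), P2ry12 at 23.7 (14.3 to 15.3) and Hcrt at 0 (0.107 to 0.128).

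Mouse reads made up 9.41 ± 3.28% of reads in subcutaneous tumours (SD, n = 4), a signal outside the comparisons, against 0.0368% in the monolayer. Among these, replicate 3 had the fewest, 2446513, and stood apart in Hbb-bs at 148220 (14960 to 34389) and Pecam1 at 82.8 (60.8 to 61.1), and replicate 4 in Col1a1 at 35864 (17232 to 20008) and Col1a2 at 6828 (3444 to 3963).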

How the results depend on the processing

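The alternatives voom, subtraction of misassigned reads and the first tumour-free pair left out were chosen after seeing the data. Counts stayed within 1.5 times the main count in all alternatives for subcutaneous tumours against monolayer and for tumour-free regions. Leaving out cross-species genes, which tests fewer genes, gave 4615 calls in brain against subcutaneous tumours, 3891 against monolayer, 247 in forebrain against hindbrain metastases, 2695 and 336 with tumour in forebrain and hindbrain, and 43 in the difference.

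For all other changed counts the cause was not tested. Forebrain against hindbrain metastases gave 204 without a filter, 39 with only the groups compared, 58 with library weights, 1026 with the block, 100 with voom and 297 to 735 without single libraries (lowest without forebrain metastasis replicate 2, highest without replicate 3). Tumour in hindbrain gave 294 with a stricter filter, 824 with weights and 291 to 804 without single libraries (291 and 324 without hindbrain metastasis replicates 2 and 1, 804 without tumour-free hindbrain replicate 1). Tumour in forebrain gave 2353 to 4976, lowest without forebrain metastasis replicate 2. The difference gave 30 without a filter, 129 with quantile normalization, 113 with median-of-ratios scaling, 660 with weights, 173 with voom, 631 with the first tumour-free pair left out and 12 to 343 without single libraries, each of which moved it by over 1.5 times. List calls fell from 86 to 13 with an estimated correlation and were 62 to 97 otherwise.

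Of 7467 values of 365 named gene results, 7072 kept direction and side of the threshold, 330 lost a call, 23 gained one and 42 changed sign, all of the last in uncalled genes near 0. CDH1 between metastases was 0 as deposited and with weights, -0.02 with median-of-ratios scaling, -0.01 with nuclear genes and voom, and -0.06 to 0.08 without single libraries. In the same comparison single libraries gave ZEB1 -0.02 to 0.19, MKI67 -0.08 to 0.24, TUBB3 -0.27 to 0.18 and L1CAM -0.05 to 0.18. With tumour in forebrain Rbfox3 was 0 with median-of-ratios scaling and 0.06 with quantile normalization, and single libraries gave -0.09 to 0.02 for Rbfox3 and -0.07 to 0.13 for Mbp. In hindbrain Mbp was -0.1 with quantile normalization and -0.04 to 0.11 without single libraries. In the difference Cldn5 was 0.03 with median-of-ratios scaling and 0 with nuclear genes, Mbp was 0.15 with quantile normalization, and single libraries gave Cldn5 -0.28 to 0.2, Mbp -0.12 to 0.07 and Cd74 -0.47 to 0.03. Between tumour-free regions Cldn5 was -0.15 to 0.26 without single libraries. Depth limits human values: 3325 to 5753 reads stand behind each tumour-free background and 3579907 to 6897852 reads behind each metastasis.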

Other observations

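No test is reported in this part. Its values and genes were chosen after the data were seen.

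Mouse transcripts of subcutaneous tumours enter no comparison. The haemoglobin genes Hbb-bs, the highest of all, and Hba-a1 averaged 54492 ± 63018 (SD, n = 4) and 9996 ± 11942. The fibrillar collagens Col1a1 and Col3a1 averaged 23226 ± 8519 and 20361 ± 7346, and the stromal gene Postn 1275 ± 271. Myeloid genes were at 6757 ± 749 for Apoe, 4177 ± 295 for Lyz2, 816.4 ± 80.4 for C1qa, 573 ± 39.2 for Cd68 and 271 ± 34.7 for Mrc1. The T cell gene Cd3e was at 0.148 ± 0.297 in these athymic animals, the astrocyte gene Gfap at 1.95 ± 1.57 and Tmem119 at 80.7 ± 12.1. The epidermal keratin genes Krt14, Krt5 and Krt10 were at 0, 0.195 and 1.61 in replicate 3, against 383 to 487, 252 to 357 and 1043 to 2147 in the others. Mouse reads expected at monolayer rates were 0.343% of the 14167201 mouse reads of these tumours, and their source was not tested.

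Single brain libraries also differed within groups. Malat1 was at 1681, 5586 and 5294 in the 3 tumour-bearing hindbrains, against 1649 to 2490 in tumour-free hindbrain. Ttr, a marker of choroid plexus, was at 1154 in tumour-bearing forebrain replicate 1 and at most 19.2 in the other libraries of that group, and Shox2 at 4.41 and at most 0.0367. The haemoglobin gene Hba-a1 was at 2.82, 4.04 and 24.4 in tumour-bearing forebrain and 16.4, 9.23 and 49.9 in tumour-bearing hindbrain.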
